A study of Homo sapiens and Mus musculus with 16 samples.

How the data were processed

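Gene-level RNA sequencing tables were analysed for 12 libraries of Karpas-299, a human T cell-derived anaplastic large cell lymphoma (ALCL) line, and for 4 libraries of mouse hepatoma cells. The Karpas-299 cells had been electroporated with the scrambled siControl or with siA-1, siA-3 or siA-1/3 against ARNT, the dimerisation partner of the aryl hydrocarbon receptor (AhR). Each siRNA group had 2 libraries with the solvent DMSO and 1 library with the AhR ligand TCDD (10 nM for 2 hours). The mouse libraries, 1 per group, were Hepa-1c1c7 cells with DMSO, Hepa-1c1c7 cells with TCDD, and BpRc1 cells (a Hepa-1c1c7 variant that lacks Arnt) carrying either wild-type ARNT isoform 1 or its S77A mutant, each with TCDD. Per the labels, RNA was purified on columns and libraries were made with a TruSeq kit.

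The deposited tables gave, for each gene, raw read counts (total and uniquely placed exon reads, intron reads and exon-exon junction reads). They also gave the authors' RPKM (reads scaled to exon length and library size) and the authors' TPM (the same scaling with a fixed total). A further deposited column of expression values equalled RPKM in 9 libraries and the raw count of total exon reads in 7, so it was not used, and neither were RPKM and TPM. The human tables were on build hg38 per the submitters' processing notes. The mouse build was not given in the sources used here, so no mouse coordinates are printed. The aligner and the counting tool were not given in the sources used here. The human tables held 45372 genes and the mouse tables held 41961. Total exon reads were 14843864 to 28727514 per human library and 20775345 to 24133783 per mouse library.

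Counts of total exon reads were scaled by TMM (trimmed mean of M values) and tested with the edgeR quasi-likelihood F test (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3) after edgeR's expression filter, two-sided, with Benjamini-Hochberg (BH) adjustment over the genes tested, an adjusted p threshold of 0.05 and no minimum fold. Knockdowns were compared within the 8 DMSO libraries (13667 genes). TCDD was compared in siControl cells and in interaction contrasts, which tested whether the TCDD response differed between each knockdown and siControl, in a fit of 8 groups over 12 libraries (14571 genes). There the spread came from the DMSO pairs, and each TCDD library was assumed to vary like them. The mean TCDD effect had siRNA as an additive term. With 1 library per group, the mouse pairs had no test: ratios of TMM-scaled counts were given with exact (Clopper-Pearson) 95% intervals, and genes with at least 100 reads in at least 1 of the compared libraries were counted at a fold of 2 or more. Intervals and floors cover counting error only, and the floor for a count of 0 was 3 reads per library, which leaves out the error of the other count. Separate cultures are not stated for the replicates, so p-values measure only the spread between these samples.

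The power of the tests was tested on simulated data in which 200 genes were changed, 50 at each fold. For siA-3 against siControl, 8% of genes changed 1.5-fold, 52% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold were called, with 8 false calls among 137. For the mean TCDD effect the shares were 62%, 92%, 98% and 100%, with 3 false calls among 179. For TCDD in siControl cells they were 4%, 22%, 84% and 98%, with 13 false calls among 117.

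The comparisons, tests, gene lists and naming rule were chosen before the data were examined. In each comparison ARNT, AHR and the measured members of the AhR battery and of the AhR and ARNT pathway components could be named. Up to 8 genes per direction with the largest log2 fold change past the threshold were named, if their mean log2 CPM (counts scaled to library size, TMM-adjusted) was at least 3, their symbols were not clone or pseudogene names, and every library of one group lay beyond every library of the other (for the mean TCDD effect, the same direction in all 4 siRNAs). Where fewer than 8 passed, up to 5 per direction that missed the threshold could follow, by smallest p. Up to 4 members of each gene list by smallest p, and for the mouse pairs the 10 highest and 10 lowest ratios among genes with at least 100 reads and up to 4 members per list by largest absolute log2 ratio, could also be named. Some genes that met the rule are not reported here. TRAF3 was given in the human libraries, because the name under which the table of siA-1 DMSO replicate 1 was deposited carries that symbol while its labels do not. The human lists were the AhR battery, AhR-linked T cell genes, AhR and ARNT pathway components, hypoxia (HIF) targets, NF-kB targets, NPM-ALK/STAT3 and ALCL genes, interferon response, p53 targets, integrated stress response and unfolded protein response (UPR), heat shock, proliferation, cholesterol synthesis, immediate early genes, ribosomal proteins, mitochondrially encoded genes, and markers of T cells, B cells, myeloid cells, epithelium and fibroblasts. Mouse lists added hepatocyte identity and other cell types. Lists with at least 3 measured members were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), BH-adjusted over the lists of a comparison, and again with an estimated correlation. Mouse list medians were ranked among 10000 random lists matched on expression.

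Each siRNA target sequence was located in the ARNT transcripts of the human annotation (GENCODE). The match to bases 2 to 8 of the guide strand, taken as the strand antisense to the stated target, was then searched in annotated 3' UTRs of 11835 tested genes. Of these, 11830 were protein-coding (99.2% of the 11931 tested protein-coding genes). Every 7-mer found in at least 50 genes (16215 of them) was ranked by z. This is the mean log2 fold change of genes with it minus that of genes without it, after 3' UTR length and GC content were regressed out, over a standard error from the spread of all genes together. The SE printed beside a difference instead uses the spread of genes with and without the 7-mer separately, so z is not their ratio. In simulated data the shifted 7-mer ranked first in 10 of 10 runs. Because the knockdowns share their siControl libraries, correlations between their fold changes were set beside 100 simulations of unchanged groups.

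Alternatives were DESeq2 size factors, no expression filter, DESeq2 (1.42.0), limma-voom, uniquely placed reads, a replicate block, an additive fit of 12 libraries, fits of only the groups compared, a mean TCDD effect without the siRNA term, leaving out each library, each siControl library alone as control, and for mouse library totals, a pseudocount of 10 reads and minimums of 20 and 500 reads. Chosen after seeing the data were total gene reads, terms for a technical split by intron share or by the share of uniquely placed reads, and a fit of the 8 libraries of higher intron share. Reads per gene do not separate ARNT isoforms and no isoform levels are reported. AHRR was read from the record AHRR_1, which overlaps another record at its locus. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.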

Results

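RNA was sequenced from 12 libraries of Karpas-299 cells, a human T cell lymphoma line, and from 4 libraries of mouse hepatoma cells. In Karpas-299, ARNT was targeted with siA-1 (isoform 1), siA-3 (isoform 3) or siA-1/3 (both isoforms, with a pair of duplexes), beside the scrambled siControl, with 2 DMSO libraries and 1 TCDD library for each siRNA. The study asks whether ARNT isoform 1, and its phosphorylation once AhR is activated, sets AhR activity in T cell malignancies. Human libraries held 14843864 to 28727514 exon reads and mouse libraries 20775345 to 24133783. Groups of 1 library have no replicate error.

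Human libraries fell apart on technical measures as well as on siRNA. Uniquely placed reads made up 94.49% to 94.99% of exon reads in 5 libraries, the 4 with TCDD and siA-1 DMSO replicate 1, and 85.59% to 86.3% in the other 7. Intron reads made up 4.132% to 4.639% of gene reads in 4 DMSO libraries (siControl replicate 1, siA-1 replicate 1, siA-3 replicate 1 and siA-1/3 replicate 2) and 5.119% to 5.933% in the other 8. The first principal component, which held 50.9% of the variance, set the 3 siA-1 libraries apart from the rest.

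ARNT itself was lower with every ARNT siRNA. ARNT (ENSG00000143437, hg38 chromosome 1, 150809713 to 150876708) stood at 132 CPM ± 3.85 (SD, n = 2) in siControl DMSO cells, 84.9 ± 1.59 with siA-1, 59.3 ± 5.25 with siA-3 and 44.6 ± 1.21 with siA-1/3. Per library the ARNT values were 135 and 130 CPM in siControl, 83.8 and 86 in siA-1, 63 and 55.6 in siA-3, and 45.5 and 43.7 in siA-1/3. The TCDD libraries gave 133, 82.4, 60.5 and 42.8 CPM in the same order. ARNT fell by 0.62 on the log2 scale with siA-1 (SE 0.12, edgeR adjusted p = 0.00873), by 1.15 with siA-3 (SE 0.12, adjusted p = 0.0135) and by 1.56 with siA-1/3 (SE 0.12, adjusted p = 0.00235). The siA-1 call missed the threshold without siControl replicate 1 (adjusted p = 0.0687) or replicate 2 (0.059), as did the siA-1/3 call (0.0744 and 0.077). The siA-3 call missed it without siControl replicate 1 (0.176), siControl replicate 2 (0.165), siA-3 replicate 1 (0.107) or siA-3 replicate 2 (0.249), while the ARNT log2 fold change stayed between -1.24 and -1.06.

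The siRNA targets matched the isoforms named for them. The siA-1 target spanned the junction of exons 4 and 5 of transcript ARNT-201, into a 45-base exon at 150842424 to 150842468 on chromosome 1. The siA-3 target spanned the junction made when that exon is skipped, from the exon at 150846263 to 150846307 to the one at 150839441 to 150839654 (transcripts ARNT-206 and ARNT-208). The siA-1/3 duplexes lay in exon 20 and across exons 20 and 21 of ARNT-201. TRAF3 (ENSG00000131323, chromosome 14, 102777476 to 102911500), a signalling adaptor, stood at 44.3 CPM in siA-1 DMSO replicate 1, at 91.3 in replicate 2 and at 103 in the siA-1 TCDD library, against 80.7 and 85 in siControl DMSO. The name under which that first siA-1 table was deposited carries the symbol TRAF3, and its labels do not.

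**Figure D1:**
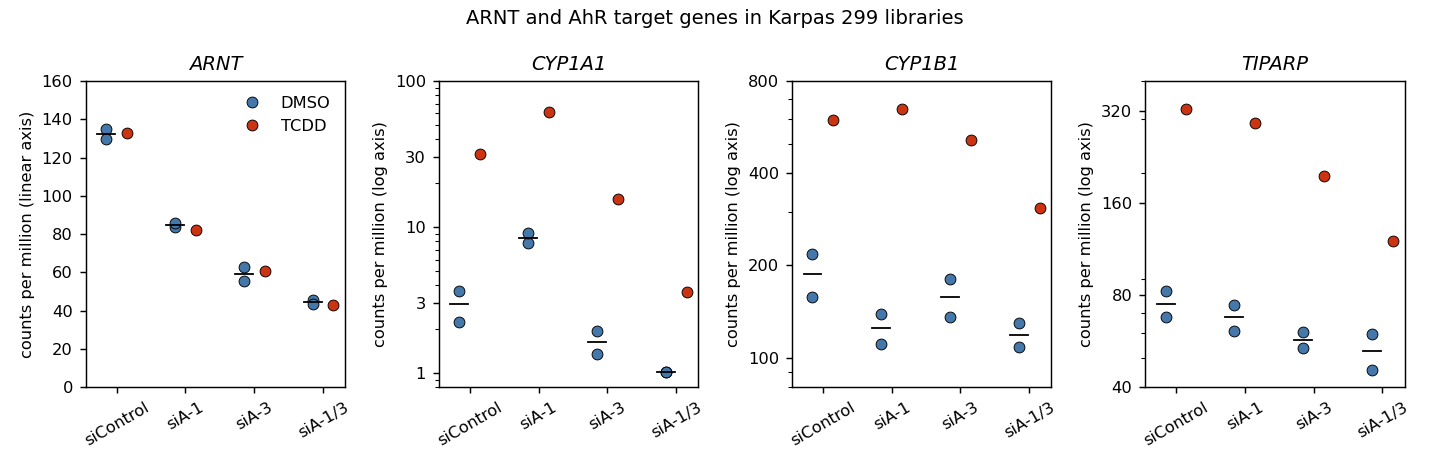
CPM of ARNT (linear axis) and of CYP1A1, CYP1B1 and TIPARP (log axes) in each Karpas-299 library, with DMSO in blue, TCDD in red and a bar at the mean of the 2 DMSO libraries. ARNT fell from 132 CPM in siControl to 44.6 with siA-1/3, and CYP1A1 with TCDD ranged from 3.62 CPM with siA-1/3 to 61 with siA-1.

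The comparison of siA-1 with siControl asked what the loss of ARNT isoform 1 did without added ligand. Genes of the NPM-ALK and STAT3 programme that drives this lymphoma fell: STAT3, its transcription factor, fell by 1.92 on the log2 scale (SE 0.21, n = 2 per group, edgeR adjusted p = 0.00242), and SOCS3, a feedback inhibitor induced by STAT3, fell by 2.38 (SE 0.32). Of the ribosomal protein genes 21 of 22 fell, and of the cholesterol synthesis genes 15 of 17 rose; as lists these 3 sets passed camera but not with correlation estimated (adjusted p = 0.193 with an estimated correlation for each). Under the naming rule, which asks for a mean log2 CPM of at least 3 and groups that do not overlap, the named rises were in LSP1 (a leukocyte actin-binding protein, log2 fold change 5.30), ASB2 (a ubiquitin ligase subunit, 4.15), CD96 (a receptor of T and NK cells, 3.81), the protease PRSS23 (3.65), the tetraspanin CD82 (3.64), the cytokine LTB (3.45), the receptor GPR84 (3.21) and CD93 (3.15). The named falls were in the antisense transcript IL21-AS1 (-3.04), the transcription factor ZBED2 (-2.92), MYBPC2 (-2.64), CYB5R3 (-2.64), RBM44 (-2.63), the ligand WNT9B (-2.55), MYPN (-2.50) and the transcription factor SOX2 (-2.44).

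Of 13667 genes tested with edgeR, 4035 (29.52%) changed with siA-1 (2180 rose and 1855 fell), 1738 of them at least 2-fold. The count was 1033 without siControl replicate 1 and 1126 without siControl replicate 2. Of the 16 genes named above, LSP1 missed the threshold without siControl replicate 1 (adjusted p = 0.0651) or replicate 2 (0.0749), and SOX2 without siControl replicate 1 (0.0518). The siA-1 replicates differed more (chi-square per degree of freedom 56.4) than those of the other siRNAs (14.1 to 26.6), and leaving out either moved most of these values. Without siA-1 replicate 1, LSP1 stood at 2.44, ASB2 at 3.16, CD96 at 2.73, PRSS23 at 2.52, CD82 at 2.87, LTB at 2.31, CYB5R3 at -3.28, IL21-AS1 at -2.65, ZBED2 at -2.35, MYBPC2 at -2.17, RBM44 at -1.99, MYPN at -1.98 and SOX2 at -1.81. Without siA-1 replicate 2 they stood at 6.18, 4.71, 4.41, 4.26, 4.12, 4.07, -2.21, -3.63, -3.89, -3.37, -3.91, -3.37 and -3.66 in that order, while GPR84 (3.18 to 3.23), CD93 (3.00 to 3.31) and WNT9B (-2.62 to -2.51) moved less.

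Among the 22 NPM-ALK/STAT3 and ALCL genes measured, 17 fell and 1 rose with siA-1 (18 and 1 adjusted over the list alone). They included PIM1 (-1.93), GZMB (-1.67), the CD30 gene TNFRSF8 (-0.89) and ALK itself (-0.63), and the receptor PDGFRB rose (1.59). The list was lower by camera (adjusted p = 5.25e-06), but not when correlation was estimated (adjusted p = 0.193 with an estimated correlation). Of 22 ribosomal protein genes 21 fell (22 adjusted over the list alone), by a median of -0.51 log2, with RPL11 at -0.90 (camera adjusted p = 2.10e-08, adjusted p = 0.193 with an estimated correlation). Of 17 cholesterol synthesis genes 15 rose (16 adjusted over the list alone), among them INSIG1 (2.02), STARD4 (1.91) and LSS (1.34), which encodes lanosterol synthase (camera adjusted p = 2.97e-07, adjusted p = 0.193 with an estimated correlation). Of 26 proliferation genes 10 fell and 1 rose, the same numbers adjusted over the list alone, with the ribonucleotide reductase subunit RRM2 at -2.35 and the replication factor MCM5 at -1.31 (camera adjusted p = 0.0229, 0.118 without siA-1 replicate 2, adjusted p = 0.193 with an estimated correlation). Of 24 interferon response genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), with RSAD2 at 2.55 and OAS3 at 1.11 (camera adjusted p = 0.00367, 0.079 without siA-1 replicate 1, adjusted p = 0.46 with an estimated correlation).

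AhR target genes moved both ways with siA-1. Of 9 AhR battery genes 3 rose and 2 fell (3 and 4 adjusted over the list alone): AHRR_1, the record read for the AhR repressor, rose by 2.67 log2, CYP1A1, the classical AhR target, by 1.51 and the quinone reductase NQO1 by 0.83, while IL1R2 (-1.45) and the amino acid transporter SLC7A5 (-1.01) fell. The list's median was -0.13, its mean 0.13 and its camera adjusted p 0.92. CYP1A1 missed the threshold without siControl replicate 1 (adjusted p = 0.078). CYP1B1 (-0.57, adjusted p = 0.0765) and TIPARP (-0.13) did not pass the test. Of 13 AhR and ARNT pathway components 8 fell, 8 also adjusted over the list alone, including EPAS1 (-1.47), HIF1A (-0.69) and the casein kinase 2 genes CSNK2A1 (-0.49), CSNK2A2 (-0.47) and CSNK2B (-0.50) (camera adjusted p = 0.0199, 0.0561 without siControl replicate 1, 0.06 without siA-1 replicate 2, adjusted p = 0.193 with an estimated correlation). AHR was read from a record that overlaps others, with 6.33% to 8.29% of its reads unique in 7 libraries and 57.5% to 60.2% in 5, and its log2 fold change turned from -0.52 to 1.40 when only unique reads were counted.

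The lists of 8 AhR-linked T cell genes (2 rose, 2 fell; camera adjusted p = 0.809), 27 HIF targets (4 rose, 10 fell; 0.125) and 19 NF-kB targets (6 rose, 1 fell; 0.162) did not pass with siA-1. Adjusted over the list alone, the numbers were 2 and 2, 5 and 10, and 6 and 1. The glycolytic genes TPI1 (-1.92) and LDHA (-1.32) fell while the glucose transporter SLC2A3 rose (1.38), the immunosuppressive cytokine IL10 fell (-1.51), and the NF-kB subunit NFKB2 rose (1.64).

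The comparison of siA-3 with siControl asked the same of isoform 3. The genes with large rises included the calgranulins S100A9 (log2 fold change 4.34, SE 0.44, n = 2 per group, edgeR adjusted p = 0.0135) and S100A8 (3.94, SE 0.63, adjusted p = 0.0472), the amino acid oxidase IL4I1 (3.78), the interleukin-7 receptor IL7R (3.23) and CD274, which encodes PD-L1 (1.80). GPR84 (2.65), COLQ (2.20), TMEM229B (2.00) and HSD11B1 (1.95) rose too. The falls named by the same rule were in the spliceosome gene TXNL4A (-2.68, SE 0.13, adjusted p = 4.72e-04), MOB4 (-2.00), SPRYD7 (-1.85), THAP12 (-1.84), GLCCI1 (-1.75), TRUB1 (-1.69), HSDL2 (-1.57) and ABCB10 (-1.52). Of all 37 genes that fell with siA-3, 26 held the match to its guide in their 3' UTR (70.3%, against 22.5% of all genes). Of the genes that fell with siA-1/3, 48.1% held that match too. For the falls, silencing through the guide is thus not separated from the loss of isoform 3.

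With siA-3, 67 of 13667 genes changed by edgeR (30 rose and 37 fell). The count was 3 without either siControl library and 2 without either siA-3 library. Of the 16 genes that the rule gave for siA-3, 1 (TXNL4A) passed without each of the 4 libraries, and every one kept its sign. DESeq2 called 372 genes, and uniquely placed reads gave 23.

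NF-kB targets stood higher with siA-3 as a group. None of the 19 passed over all genes, and 10 rose and 0 fell adjusted over the list alone, with BCL2A1 at 2.57, EBI3 at 1.88 and RELB at 0.62; all 19 values were positive (camera adjusted p = 7.62e-09, adjusted p = 0.0716 with an estimated correlation). Of 5 myeloid markers S100A9, S100A8 and CD68 (1.57) rose, 3 also adjusted over the list alone (camera adjusted p = 1.47e-04, adjusted p = 0.106 with an estimated correlation), while CSF1R (0.03) and ITGAM (0.41) did not pass. Of 8 T cell identity genes 1, IL7R, rose (2 adjusted over the list alone; camera adjusted p = 0.00304, adjusted p = 0.167 with an estimated correlation). Of 24 interferon genes OAS3 (1.59) rose, 1 also adjusted over the list alone (camera adjusted p = 0.00193, adjusted p = 0.474 with an estimated correlation). Of 17 cholesterol synthesis genes 0 passed over all genes, and 5 rose and 1 fell adjusted over the list alone, HMGCS1 at 0.76 and LSS at 0.53 among them (camera adjusted p = 2.13e-04, adjusted p = 0.328 with an estimated correlation). The 9 AhR battery genes held no gene past the test on either scale, with CYP1A1 at -0.84 and TIPARP at -0.39 (median -0.24, camera adjusted p = 0.152).

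The comparison of siA-1/3 with siControl asked what the loss of both isoforms did. The rises named by the rule were in IL7R (log2 fold change 4.15, SE 0.31, n = 2 per group, edgeR adjusted p = 0.00235), S100A9 (2.84), the survival gene BCL2A1 (2.80, SE 0.42, adjusted p = 0.0411), the urokinase receptor PLAUR (2.65), GPR84 (2.40), the complement regulator CD59 (2.36), the phosphatase gene DUSP1 (2.21) and CD274 (2.13). Besides ARNT, the named falls included LY86-AS1 (-2.50), the fucosyltransferase FUT7 (-1.88), TNFRSF19 (-1.88), REPS2 (-1.72), the lipid phosphatase INPP4B (-1.68) and NPHP4 (-1.57).

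With siA-1/3, 75 genes changed by edgeR (46 rose and 29 fell). The count was 1 without siControl replicate 1, 0 without siControl replicate 2, 16 without siA-1/3 replicate 1 and 37 without siA-1/3 replicate 2. Of the 16 genes that the rule gave, ARNT among them, 0 passed without each of the 4 libraries, and every one kept its sign. The size of the BCL2A1 rise moved with the library left out. Its log2 fold change was 2.80 with all libraries and 2.04 without siA-1/3 replicate 1. It was 2.49 without siControl replicate 1 and 3.22 without siControl replicate 2. DESeq2 called 462 genes, and uniquely placed reads gave 6.

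Of 19 NF-kB targets 5 rose with siA-1/3 (10 adjusted over the list alone): BCL2A1, CD83 (2.44), ICAM1 (1.22), the inhibitor NFKBIA (1.16) and RELB (1.07). The list was higher by camera (adjusted p = 1.62e-09, adjusted p = 0.0624 with an estimated correlation). Of 9 AhR battery genes 0 passed over all genes, and 5 fell and 1 rose adjusted over the list alone, with CYP1A1 at -1.53 (adjusted p = 0.12), AHRR_1 at -1.39, NQO1 at -0.38 and IL1R2 at 0.94 (camera adjusted p = 0.0121, 0.0586 without siControl replicate 2, 0.126 without siA-1/3 replicate 2, adjusted p = 0.312 with an estimated correlation). Of 8 AhR-linked T cell genes 0 passed over all genes and 2 fell adjusted over the list alone, the cytokine IL22 (-1.53) and IKZF3 (-1.54) (camera adjusted p = 0.0237, 0.0815 without siA-1/3 replicate 2, adjusted p = 0.312 with an estimated correlation). Of 22 NPM-ALK/STAT3 and ALCL genes CD274 and HIF1A (0.63) rose and 0 fell (6 and 1 adjusted over the list alone), while STAT3 stood at 0.30 and ALK at -0.04 (camera adjusted p = 0.00653, adjusted p = 0.312 with an estimated correlation).

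**Figure D2:**
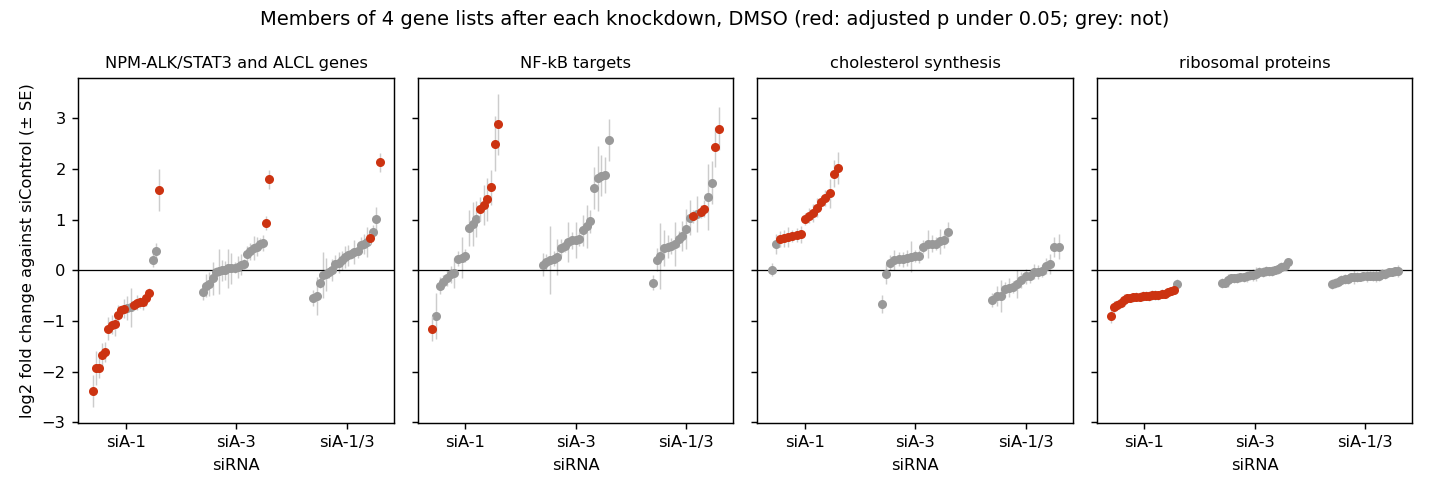
Log2 fold change (vertical axis) of the measured members of selected gene lists in the knockdown comparisons, each with its standard error, with members at an adjusted p under 0.05 in red. With siA-1, 17 of 22 NPM-ALK/STAT3 and ALCL genes fell and 15 of 17 cholesterol synthesis genes rose.

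Set against each other directly, siA-1 and siA-3 differed in 4065 genes by edgeR, 29.74% of those tested (2164 higher and 1901 lower with siA-1). The genes named by the rule as higher were ASB2 (log2 difference 4.05, SE 0.58, adjusted p = 0.00322), SCUBE1 (3.99), CD96 (3.91), the integrin ITGA4 (3.71), the pseudokinase TRIB2 (3.65), RGPD5 (3.64), LSP1 (3.53) and the thrombin receptor F2R (3.44). Those named as lower were S100A9 (-4.73, SE 0.46, adjusted p = 0.00125), IL7R (-4.14), SYN1 (-3.79), RBM44 (-3.62), the channel AQP9 (-3.56), ANKRD22 (-3.51), SOX2 (-3.49) and BCL2A1 (-3.47). Leaving out 1 library in turn moved ASB2 (3.06 to 4.62), CD96 (2.83 to 4.51), TRIB2 (2.60 to 4.24), ITGA4 (3.07 to 4.13), RGPD5 (3.19 to 4.33), RBM44 (-4.89 to -2.98), AQP9 (-5.44 to -2.78) and SOX2 (-4.70 to -2.86). Moves were smaller for SCUBE1 (3.75 to 4.25), IL7R (-4.27 to -4.03) and BCL2A1 (-3.66 to -3.29). CYP1A1 was higher with siA-1 (2.35, SE 0.33, adjusted p = 0.00316), as was AHRR_1 (2.93). ARNT was higher with siA-1 by 0.53 log2, past the threshold with all libraries but not without siA-3 replicate 1 (adjusted p = 0.0629) or replicate 2 (0.149). The count of genes was 1356 without siA-3 replicate 1 and 780 without siA-3 replicate 2, and LSP1 stood at 0.67 without siA-1 replicate 1 (adjusted p = 0.109) and missed the threshold without siA-3 replicate 1 (0.139) or replicate 2 (0.14), as did AQP9 without siA-3 replicate 2 (0.0501).

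Relative to siA-3, 18 of 22 NPM-ALK/STAT3 and ALCL genes were lower with siA-1 and 1 was higher, the same adjusted over the list alone, with STAT3 at -2.03 and SOCS3 at -2.42 (camera adjusted p = 1.84e-07, adjusted p = 0.257 with an estimated correlation). Of 22 ribosomal protein genes 21 were lower (22 adjusted over the list alone; 4.46e-07, adjusted p = 0.345 with an estimated correlation). Of 17 cholesterol synthesis genes 12 were higher, 12 also adjusted over the list alone (4.19e-04, adjusted p = 0.451 with an estimated correlation). Of 27 HIF targets 14 were lower and 3 higher (15 and 4 adjusted over the list alone; camera adjusted p = 0.0198, 0.148 without siA-1 replicate 2, adjusted p = 0.593 with an estimated correlation). Of 9 AhR battery genes 3 were higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.579).

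Fold changes of the knockdowns were compared across 11449 genes, which are not independent replicates. Genes such as IL7R, S100A9, CD274, GPR84, PLAUR, DUSP1 and COLQ rose, and ARNT and FUT7 fell, with both siA-3 and siA-1/3. Of these, GPR84 (3.21), PLAUR (2.11) and COLQ (0.94) also rose with siA-1, and ARNT (-0.62) also fell with it. The siA-3 and siA-1/3 knockdowns shared 9 risen and 2 fallen genes, where independent lists would share 0.101 and 0.0785, and 0 genes went opposite ways. Their correlation was 0.46 (0.49 simulated from the shared siControl libraries with no effect), and their covariance 0.069 (0.036 simulated). With siA-1 and siA-3, CD274 fell in the former (-0.76) and rose in the latter (1.80), while IL4I1 (2.60 and 3.78) and CXCR3 (3.41 and 2.97) rose in both. The siA-1 and siA-3 knockdowns shared 14 rises (4.79 for independent lists) and 10 falls (5.02), with 10 genes going opposite ways (9.97). For siA-1 and siA-1/3 the numbers were 18 (7.34), 8 (3.94) and 18 (10.9). The covariance was 0.056 for siA-1 and siA-3 (0.036 simulated; correlation 0.20, 0.49 simulated) and 0.036 for siA-1 and siA-1/3 (0.037 simulated; correlation 0.12, 0.50 simulated). Part of any excess may come from the shared controls, since each part of them, once divided, holds 1 library. The numbers for independent lists do not allow for the shared siControl libraries, and the overlap of lists was not simulated.

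TCDD in siControl cells asked how these cells respond to an AhR ligand within 2 hours. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725536) rose from 2.96 CPM ± 0.988 (SD, n = 2) to 31.6 (log2 fold change 3.41, SE 0.29, edgeR adjusted p = 0.0146). TIPARP (ENSG00000163659, chromosome 3, 156673235 to 156706770), a feedback ADP-ribosyltransferase, rose from 75 ± 10.4 to 324 CPM (2.11, SE 0.21, adjusted p = 0.0227). ULBP3, a ligand of the killer receptor NKG2D, rose from 19.7 ± 1.77 to 209 CPM (3.41, SE 0.31, adjusted p = 0.0178). CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) stood at 188 ± 42.7 CPM with DMSO and 595 with TCDD and missed the threshold (1.66, adjusted p = 0.124). The nearest misses were FUT7 (1.38, adjusted p = 0.0564), the Wnt co-receptor LRP5 (1.63, 0.0564), DOK1 (1.26), the Hedgehog receptor PTCH1 (1.43) and F2RL3 (1.47) among higher genes, and PRAG1 (-1.33, 0.135), RPL17-C18orf32 (-1.43), NBPF14 (-1.06), NBPF19 (-1.78) and CD274 (-0.97) among lower ones. In all 4 genes of 14571 passed, the fourth being AC087632.1 (-5.16), and 61 did by DESeq2.

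Without siControl replicate 1 the count was 1, and CYP1A1 (adjusted p = 0.125), TIPARP (0.238) and ULBP3 (0.238) missed the threshold. Without siControl replicate 2 it was 2, and TIPARP (0.153) and ULBP3 (0.157) missed it while CYP1A1 passed (0.0449). Of 10 AhR battery genes 2 rose (4 adjusted over the list alone; camera adjusted p = 2.60e-10, adjusted p = 0.0571 with an estimated correlation). Of 13 mitochondrially encoded genes 0 passed on either scale, with a median of -0.35 (camera adjusted p = 4.96e-05, 0.0547 without siControl replicate 1, adjusted p = 0.715 with an estimated correlation).

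Over all 4 siRNAs, TCDD raised a small set of genes led by AhR targets. CYP1A1 rose by 2.94 log2 (SE 0.20, 4 TCDD and 8 DMSO libraries, edgeR adjusted p = 1.62e-04), TIPARP by 1.81 (SE 0.14, adjusted p = 2.71e-04) and CYP1B1, another AhR-induced cytochrome P450, by 1.79 (SE 0.15, adjusted p = 4.77e-04). These 3 genes passed without each of the 12 libraries. The cell cycle repressor E2F7 (1.64), LRP5 (1.38), the cell cycle inhibitor CDKN1A (1.21), ARHGEF10 (1.09) and the stress phosphatase subunit PPP1R15A (1.04) rose as well, and with 1 of the 12 libraries left out in turn they passed 4, 10, 3, 9 and 6 times in that order. The 4 lower genes that met the naming rule were NBPF19 (-1.38), NBPF14 (-0.88), NBPF26 (-0.66) and NBPF9 (-0.61), members of a family of near-identical copies. With 1 of the 12 libraries left out in turn they passed 9, 12, 4 and 5 times in that order. Only 0.165% to 4.74% of NBPF19 reads were uniquely placed, and its log2 fold change was 1.08 when only those were counted.

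In the mean TCDD effect 34 of 14571 genes changed by edgeR (29 rose and 5 fell). The count was 6 without siControl TCDD or without siA-3 TCDD, 9 without siA-1 TCDD or siA-3 DMSO replicate 1, 14 without siControl DMSO replicate 2, 16 without siControl DMSO replicate 1, 17 without siA-1 DMSO replicate 2, 18 without siA-3 DMSO replicate 2 and 74 without siA-1 DMSO replicate 1. Within the 8 libraries of higher intron share it was 96, 27 of them shared with the 34. With a term for the intron-share set it was 15. The TCDD libraries were also all of the class with more uniquely placed reads, so the TCDD comparison overlaps that technical difference except through siA-1 DMSO replicate 1.

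Of 10 AhR battery genes 3 rose with TCDD over the 4 siRNAs (5 adjusted over the list alone), NFE2L2 (0.44) and SLC7A5 (0.34) being the others on the list alone. This list was higher by camera (adjusted p = 1.46e-08) and also with correlation estimated (adjusted p = 0.0172 with an estimated correlation). Of 13 mitochondrially encoded genes 0 passed over all genes and 13 fell adjusted over the list alone, with MT-ND4L at -0.81 and MT-CO1 at -0.44 (camera adjusted p = 3.11e-11, adjusted p = 0.466 with an estimated correlation). The mitochondrial share of reads also varied among DMSO libraries: it was 4.372% to 4.83% in the 4 DMSO libraries of lower intron share, 3.198% to 5.312% in the other 4 DMSO libraries and 2.953% to 3.483% with TCDD. Of 8 AhR-linked T cell genes 1 rose (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.192). The lymphocyte factor IRF4 (0.60) rose among 22 ALCL genes (1 also adjusted over the list alone; 0.746), CDKN1A among 20 p53 targets (1 also adjusted over the list alone; 0.446), and the phosphatase gene DUSP2 (0.67) among 17 immediate early genes (2 adjusted over the list alone; 0.0121, 0.0575 without siA-1/3 DMSO replicate 2, 0.096 without siA-3 TCDD, adjusted p = 0.466 with an estimated correlation).

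Interaction contrasts asked whether each knockdown changed the TCDD response. With siA-1/3, CYP1A1 went from 1.02 CPM ± 0.00301 (SD, n = 2) to 3.62 and TIPARP from 52.7 ± 9.9 to 120. With siA-1, CYP1A1 went from 8.39 ± 0.93 to 61 and TIPARP from 67.8 ± 9.42 to 291, and with siA-3 they went from 1.64 ± 0.407 to 15.5 and from 57.1 ± 4.86 to 196. The CYP1A1 response differed from that of siControl by -1.58 log2 with siA-1/3 (SE 0.48), by -0.55 with siA-1 (SE 0.41) and by -0.18 with siA-3 (SE 0.45), and that of TIPARP by -0.92 (SE 0.31), -0.01 (SE 0.31) and -0.33 (SE 0.31). None of these 6 values passed (edgeR adjusted p = 1), and for siA-1/3 the adjusted p over the AhR battery alone was 0.0846 for CYP1A1 and 0.0846 for TIPARP.

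For siA-1, 0 genes passed the interaction test by edgeR, 118 had an unadjusted p under 0.05, DESeq2 gave 1 and limma-voom 0. Without siA-1 DMSO replicate 2 edgeR gave 11. For siA-3 and siA-1/3 edgeR gave 1 gene each, AC087632.1, chosen for naming after its values were seen, and DESeq2 gave 4 and 6. For siA-3 the count was 1, a different gene, without siControl DMSO replicate 2, and 0 without siControl DMSO replicate 1 or either siA-3 DMSO library, and for siA-1/3 it was 0 without siControl DMSO replicate 1 or 2 or siA-1/3 DMSO replicate 1 or 2. Unadjusted p was under 0.05 for 88 genes with siA-3 and 139 with siA-1/3, and limma-voom called 0 in both. Among the lower values that missed the threshold (adjusted p = 1), named by smallest p, were those of ULBP3 for siA-1 (-2.68, SE 0.46) and siA-1/3 (-2.28, SE 0.47), of SLX1A (-2.08) and the cytokine TNF (-1.12) for siA-1, of the transcription factor MAFF for siA-3 (-2.13) and siA-1/3 (-2.32), and of GPR157 (-2.32) for siA-1/3. Among the higher ones PRAG1 stood at 0.85, 0.77 and 0.91 with siA-1, siA-3 and siA-1/3, and CD274 at 0.87 with siA-3 and 0.98 with siA-1/3. ULBP3 rose with siA-1 before any TCDD (3.10 log2, adjusted p = 0.00179), so its DMSO level there was 167 CPM ± 71.6. The AhR battery as a list responded less with siA-1/3 by camera (adjusted p = 0.0451, 0.23 without siControl DMSO replicate 1, 0.502 without siA-1/3 DMSO replicate 1, adjusted p = 0.847 with an estimated correlation), with 0 of 10 members past the test on either scale.

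**Figure D3:**
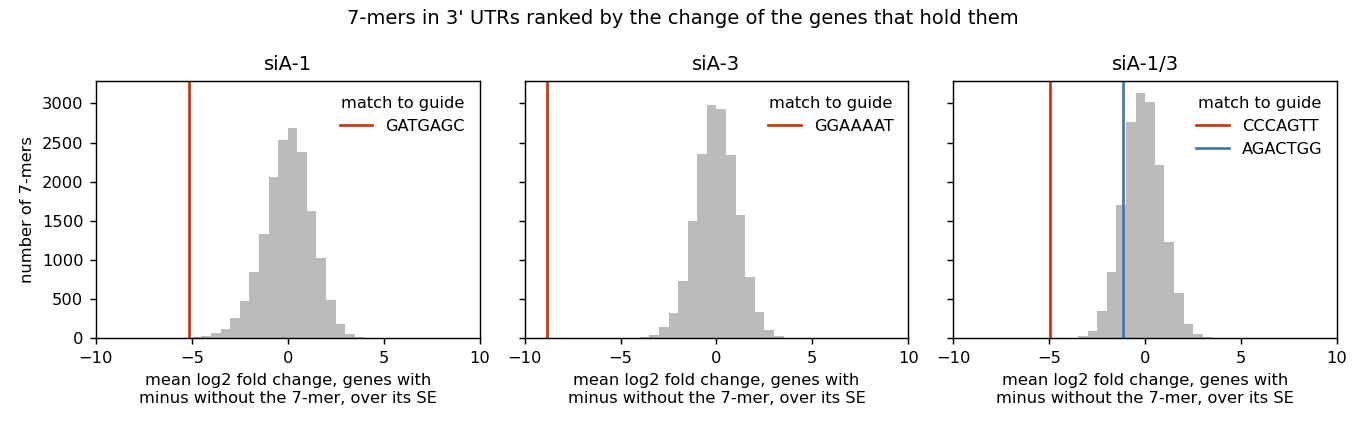
Number of 7-mers (vertical axis) by the z score of their mean log2 fold change difference, genes with the 7-mer in the 3' UTR minus genes without it, with lines at the matches to the siRNA guides. The guide matches of siA-3 and of the first siA-1/3 duplex ranked 1 of 16215 by z and that of siA-1 ranked 6.

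Genes whose 3' UTR matched the guide seed (bases 2 to 8) were lower with each siRNA. With siA-3, genes holding GGAAAAT had a mean log2 fold change lower than other genes by -0.100 (SE 0.011), the lowest z of 16215 7-mers (-8.82), and 26 of the 37 fallen genes held it (70.3%, against 22.5% of all genes). Shares of fallen genes, unlike z, were not adjusted for 3' UTR length or GC content. GGAAAAT was also held by 48.1% of the 27 genes with a 3' UTR that fell with siA-1/3, and by 18.1% of those that fell with siA-1. With the first siA-1/3 duplex, CCCAGTT ranked 1 by z (-0.070, SE 0.012), and AGACTGG, the match of the other duplex, lay at percentile 14.89, while the match to the passenger strand of that duplex, GAGCAAA, ranked 5 (-0.058, SE 0.015) and was held by 33.3% of the fallen genes (13.4% of all genes). With siA-1, GATGAGC ranked 6 by z (-5.16, difference -0.165, SE 0.032), and 176 of 1734 fallen genes held it (10.1%, against 7.16% of all genes). It was held by 13.5% of the 37 genes that fell with siA-3 and by 22.2% of the 27 that fell with siA-1/3. The passenger match ACCTGGC lay at percentile 0.333. The 5 7-mers ahead of GATGAGC (z -5.76 to -5.18) hold no full match to either strand of the ARNT siRNAs. Among these, GCCTGGC (z -5.74) differs from the passenger match only in its first base.

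In the mouse Hepa-1c1c7 pair, AhR battery genes stood higher with TCDD, with 1 library per group. Cyp1a1 was 44.2 times as high with TCDD as with DMSO (95% interval 38.6 to 50.7), Tiparp 15.7 times (14.3 to 17.2), Cyp1b1 8.26 times (6.06 to 11.5), Cyp2s1 5.53 times (4.91 to 6.25) and the aldehyde dehydrogenase Aldh3a1 4.1 times (3.65 to 4.61). Nqo1 (2.34) and Nfe2l2 (2.3), which encodes the antioxidant regulator NRF2, were higher too. Other high ratios were those of Lars2 (21.3), the pro-apoptotic Bmf (13.2), Rnf39 (10.8), Zfp28 (9.51), Mpp2 (6.6) and Tmcc3 (5.22). Lars2, a mitochondrial tRNA synthetase gene, had 14014 reads against 732 in the library in which reads on genes annotated as rRNA were 3.313% of gene reads, against 0.09983% with DMSO. Arnt (1.04, 0.961 to 1.12) did not differ beyond counting error, and Ahr was lower (0.771, 0.723 to 0.823). The lowest ratios included Gm9747 (0 against 681 reads, at least 165-fold lower by the 95% interval, 204-fold at the floor of 3 reads), Nuak2 (0.32), Kcnk5 (0.341), Ppp1r3c (0.35), Ankrd1 (0.351) and Id1 (0.386).

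Of 9557 mouse genes 140 differed at least 2-fold with TCDD (121 higher and 19 lower). Of 13 AhR battery genes 7 were at least 2-fold higher and 0 lower (median log2 ratio 1.20, percentile 100 of random lists). Immediate early genes had a median of -0.49 (percentile 0) with 1 of 14 at least 2-fold higher, and HIF targets a median of -0.02 with 3 of 24 higher, Ndrg1 (3.74), Pfkfb3 (2.73) and Ddit4 (2.29).

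**Figure D4:**
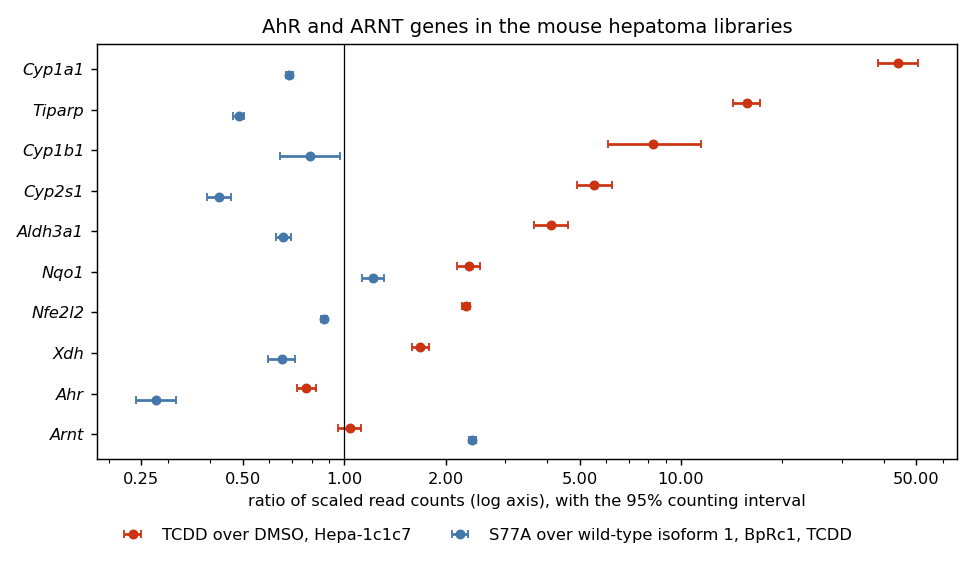
Ratios of scaled read counts (log axis) of AhR and ARNT genes in mouse hepatoma libraries, TCDD over DMSO in Hepa-1c1c7 (red) and S77A over wild-type isoform 1 in BpRc1 with TCDD (blue), with 95% counting intervals and 1 library per group. Cyp1a1 stood at 44.2 in the former and at 0.688 in the latter.

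The BpRc1 pair asked what the S77A mutation of ARNT isoform 1 does under TCDD. Most AhR targets were lower with S77A: Tiparp at a ratio of 0.486 (0.469 to 0.504), Cyp2s1 at 0.426 (0.392 to 0.462), Aldh3a1 at 0.66, Cyp1a1 at 0.688 (0.673 to 0.703) and Cyp1b1 at 0.793 (0.644 to 0.974), while Nqo1 (1.22) and Slc7a5 (1.44) were higher. Ahr was lower as well (0.277, 0.241 to 0.316), and Arnt was higher (2.4, 2.35 to 2.46), with 20000 reads against 9562. Arnt stood at 932 CPM with S77A and 388 with wild type, against 63.7 in Hepa-1c1c7 with TCDD. The S77A library lay above that Hepa-1c1c7 library in CPM for Cyp1a1 (615 against 424) and Aldh3a1 (97.8 against 65.5). It lay below for Tiparp (201 against 329), Cyp2s1 (37.4 against 78.1) and Cyp1b1 (7.46 against 16.5). Of 13 AhR battery genes 2 were at least 2-fold lower and 0 higher (median log2 ratio -0.33, percentile 0.935). Liver genes were lower in the S77A library, with Alb (albumin) at 0.0539, Rbp4 at 0.133 and Apoe at 0.297, and 4 of 7 hepatocyte identity genes at least 2-fold lower (median -1.67, percentile 0). Of 14 immediate early genes 6 were at least 2-fold higher (median 0.68, percentile 100), among them Ier3 (8.38), Klf2 (6.47), Dusp1 (3.82) and Fos (3.15). Of 10 heat shock genes 2 were at least 2-fold lower (median -0.63, percentile 0), Hsp90aa1 (0.315) and Hspe1 (0.415).

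Between the BpRc1 libraries 670 of 9606 genes differed at least 2-fold (355 higher and 315 lower with S77A), against 140 between the Hepa-1c1c7 libraries. The highest ratios included Olfr498 (242 against 0 reads, at least 74.9-fold higher by the 95% interval, 92.7-fold at the floor), the collagen gene Col6a1 (85.5, 43.1 to 199), Ms4a4d (85.1), the nucleoside transporter Slc29a1 (69.2) and Lsp1 (60.4). The lowest included the coagulation factor gene F5 (1 against 811 reads) and the protease gene Napsa (0 against 542 reads, at least 127-fold lower by the 95% interval, 157-fold at the floor).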

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

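Chosen only after the result was seen were the tests of the first siA-1 library, of a loss shared with siA-1/3, and of the Ahr and Arnt transcripts in the BpRc1 lines. The transcript AC087632.1 (ENSG00000259316, chromosome 15) had a TCDD response that differed from that of siControl by 4.34 log2 with siA-3 (edgeR adjusted p = 0.0404) and by 4.83 with siA-1/3 (adjusted p = 0.0176), which an interaction test marked as a difference between groups. DESeq2 also called it, but limma-voom did not, and the call was lost when any 1 of the DMSO libraries compared was left out. It had 16 reads in siControl TCDD and 5 in siA-1 TCDD, against 234 to 477 in the other 10 libraries, and since each TCDD group held 1 library, the spread between TCDD libraries of a group was not measured and a difference between single libraries was not excluded. A pair of measures outside the main counts stood apart in the Hepa-1c1c7 TCDD library: intron reads made up 10.97% of gene reads (4.476% to 5.294% in the other mouse libraries), and reads on genes annotated as rRNA made up 3.313% (0.07574% to 0.1201% in the others).

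With siA-1, 4035 genes changed, against 67 with siA-3 and 75 with siA-1/3, among them falls in STAT3 and SOCS3. These counts share 1 estimate of the spread, and the gap between them depends on it. The siA-1 replicates differed more (chi-square per degree of freedom 56.4) than the other pairs (14.1 to 26.6). Silencing through the guide seed may contribute to the siA-1 changes, since the siA-1 guide match ranked 6 of 16215 7-mers (percentile 0.037, z -5.16). The 5 before it (z -5.76 to -5.18) hold no full match to either strand of the ARNT siRNAs, although GCCTGGC among them differs from the passenger match ACCTGGC only in its first base. Whether seed silencing was the whole cause stays open: 89.9% of the fallen genes held no guide match, but only 847 genes held it while 1734 fell. Most fallen genes thus had to lack it, and genes without a match can fall indirectly. The first siA-1 DMSO library was not the only source of the siA-1 changes. In siA-1 TCDD against siControl TCDD, 83.9% of the called genes showed at least 50% of their change in the same direction. That is 1 pair of libraries, so how far the first library enlarged the changes stays open. On the first principal component it stood at 78.86, against 46.86 for replicate 2 and 50.22 for siA-1 TCDD. The siA-1 changes were mostly not shared by siA-1/3: over the same genes the slope of the siA-1/3 log2 fold change on that of siA-1 was 0.09. This was so although siA-1/3 lowered total ARNT further. Isoform levels were not measured, so it is unknown how far isoform 1 fell with siA-1/3. The slope therefore cannot exclude a loss of isoform 1 as the cause. What also remains open is another effect of the siA-1 duplex or an effect of losing isoform 1 while isoform 3 is kept, which these libraries cannot separate.

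With TCDD over the 4 siRNAs, CYP1A1, TIPARP and CYP1B1 led 29 risen genes. Against a difference in the share of uniquely placed reads as the cause, 96.6% of the rises showed at least 50% of their change between siA-1 TCDD and the first siA-1 DMSO library, which share that class. This explanation was not excluded, since that is 1 pair of libraries, which also helped to choose these genes. The intron shares of the pair differ as well (5.656% and 4.132%). For the lower NBPF genes, whose median log2 ratio between these libraries was -0.37, a difference in uniquely placed reads stays open too. Against a difference between the intron-share sets, 100% of the rises showed at least 50% of their change within the 8 libraries of higher intron share. It was not excluded, since these libraries were among those that chose the genes. Within them TCDD also coincides with the class of uniquely placed reads, and a term for the intron-share set lowered the count of genes. Among 81 splits of the libraries 3, the real split included, gave at least as many genes as the real 34. The 2 others gave 1480 (the 4 libraries of lower intron share) and 917 (3 of these with siA-1 DMSO replicate 2), which points to a structure of the samples. The libraries are thus not interchangeable, and the splits cannot exclude chance. Within the 8 libraries of higher intron share the value was 96 genes, 27 shared with the 34.

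In the BpRc1 pair most AhR targets were lower with S77A, such as Tiparp and Cyp2s1. Other differences between the transduced lines may account for this, since 670 genes were at least 2-fold apart, against 140 for TCDD in Hepa-1c1c7. Lower Ahr may also account for it, its ratio being 0.277. Less total Arnt transcript was excluded for these libraries, its ratio being 2.4. Reads per gene do not separate the introduced ARNT from the cells' own transcript, and ARNT protein was not measured here. With 1 library per line, the mutation and these differences were not separated.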

How the results depend on the processing

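The alternatives with total gene reads, a term for a technical split, or the 8 libraries of higher intron share were chosen only after the result was seen. The siA-1 count (4035 genes) and the siA-1 against siA-3 count (4065) stayed within 1.5 times under DESeq2 size factors, no filter, DESeq2, limma-voom, uniquely placed reads, total gene reads and the intron-share term. They moved to 6883 and 6887 in the additive fit of 12 libraries, and to 2176 and 2521 with only the groups compared. That last fit takes the spread from those groups alone, with fewer libraries, and it lowered the siA-1 count while it raised that of siA-3. The gap between these counts thus depends on how the spread is shared. The siA-1 replicates differed more (chi-square per degree of freedom 56.4) than the other pairs (14.1 to 26.6). For siA-3 (67) and siA-1/3 (75), no filter gave 679 and 829, DESeq2 372 and 462, uniquely placed reads 23 and 6, and the additive fit 1339 and 1503; only the 2 groups gave 521 for siA-3, and the intron-share term 156 for siA-1/3. Replicate numbers did not pair the samples across all groups (correlations of deviations 0.41 for siControl and siA-3, -0.33 for siA-1/3 with either of them, and -0.06 to 0.04 for pairs with siA-1), where the negative values follow the intron-share sets, in which siA-1/3 replicate 2 goes with replicate 1 of the others, and a replicate block gave 28 for siA-3 and 12 for siA-1/3. TCDD in siControl cells (4) gave 168 with no filter, 61 by DESeq2, 7 by limma-voom and 10 with total gene reads. The mean TCDD effect (34) gave 240 with no filter, 146 by DESeq2, 2422 with uniquely placed reads, 15 with the intron-share term, 5 with no siRNA term, 2850 with a uniqueness term (estimable only through siA-1 DMSO replicate 1) and 96 within the 8 libraries of higher intron share. Interaction counts for siA-1, siA-3 and siA-1/3 (0, 1 and 1 by edgeR; 118, 88 and 139 genes at an unadjusted p under 0.05) were 43, 35 and 46 with no filter and 1, 4 and 6 by DESeq2; for siA-3 and siA-1/3 they were 0 and 0 by limma-voom, 0 and 0 with uniquely placed reads, 2 and 2 with total gene reads, and 0 and 0 with the intron-share term. A minimum of 20 reads gave 317 genes for Hepa-1c1c7 (140) and 1104 for S77A (670), and a minimum of 500 gave 370 for S77A, since the minimum sets which genes are counted. With an estimated correlation the lists past the threshold went from 6 to 0 for siA-1, 8 to 0 for siA-3, 7 to 0 for siA-1/3, 5 to 0 for siA-1 against siA-3, 2 to 0 for TCDD in siControl cells, 4 to 1 for the mean TCDD effect and 1 to 0 for the siA-1/3 interaction. With siControl replicate 1 or 2 alone the correlations were 0.25 and 0.26 for siA-1 and siA-3, 0.18 and 0.19 for siA-1 and siA-1/3, and 0.54 and 0.53 for siA-3 and siA-1/3. Leaving out 1 library gave 1033 to 5341 genes for siA-1, 2 to 3 for siA-3, 0 to 37 for siA-1/3, 780 to 5477 for siA-1 against siA-3, 1 to 2 for TCDD in siControl cells, 6 to 74 for the mean TCDD effect, and 0 to 11, 0 to 1 and 0 to 0 for the interactions; lists past the threshold numbered 4 to 8, 7 to 9, 5 to 8, 3 to 7, 1 to 4, 2 to 5, 0 to 2, 0 to 1 and 0 to 1 in the same order. A lone library was assumed to vary like the other groups, and a TCDD library could not be left out of the siControl TCDD or interaction comparisons, which then have no estimate. Uniquely placed reads reversed AHR with siA-1 (1.40), in siA-1 against siA-3 (1.17) and with TCDD (2.24), HIF1A (0.60) and NBPF19 (1.08) with TCDD, and Gm49325 in Hepa-1c1c7 (0.57); TRAF3 in siA-1 against siA-3 ranged from -0.54 without siA-1 DMSO replicate 2 to 0.51 without replicate 1. Except for the minimum and library settings, the cause was not tested. Unique reads made up 47.7% to 52.6% of HIF1A reads in the class with fewer uniquely placed reads and 99.6% to 99.9% in the other. For AHR these shares were 6.33% to 8.29% and 57.5% to 60.2%. Unique counts of both genes thus differ by class, and all TCDD libraries are in the higher class. The reversals of AHR and HIF1A therefore cannot be read as changes of expression. Of the values of named genes under alternatives, 2906 kept their side of the threshold or, without a test, stayed within their counting interval, 266 were no longer past the threshold, 90 were newly past it, 32 without a test moved and 7 reversed; a change of sign was counted among the 2906 where neither value was past the threshold, such as TIPARP in the siA-1 interaction (-0.01, with 0.14 without siA-1 DMSO replicate 1). At these depths, in simulated data, 8% of genes changed 1.5-fold were called for siA-3, 4% for TCDD in siControl cells and 62% for the mean TCDD effect, which used more libraries; depth itself was not varied.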

Other observations

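Lists not described above are given here for siA-1, each with its camera adjusted p, and none of those tested passed camera. Of all genes tested, 29.52% were called with siA-1, so members called at about that share do not set a list apart. Of 20 p53 targets 7 rose and 1 fell (7 and 1 adjusted over the list alone; 0.142), among them the antiproliferative BTG2 (1.78) and the cell cycle inhibitor CDKN1A (1.41), while the nuclease AEN fell (-2.28). Of 20 integrated stress response and UPR genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; 0.809; median -0.13, mean 0.10), with the chaperones DNAJB9 (2.14) and HSPA5 (0.98) up and the transcription factor ATF5 (-2.03) down. Of 13 heat shock genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; 0.162), including the mitochondrial chaperones HSPE1 (-0.81) and HSPD1 (-0.65). Of 17 immediate early genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; 0.892; median -0.26, mean 0.56), with the nuclear receptor NR4A3 (5.76) and KLF2 (4.83) up and JUN (-0.94) down. Of 8 T cell identity genes the coreceptor CD4 rose (0.48; 1 adjusted over the list alone; 0.551), of 5 myeloid markers the integrin ITGAM (2.05) and CD68 (1.52) rose (2 adjusted over the list alone; 0.493; median -0.01, mean 0.55), and of 3 epithelial markers KRT18 rose (0.72; 2 rose and 1 fell adjusted over the list alone; 0.545). The 13 mitochondrially encoded genes (median 0.03, 0.92) and 2 fibroblast markers (median 0.32, too few for camera) had 0 past the test on either scale, and 1 B cell marker, PAX5, stood at -0.57.

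With siA-3, camera was past the threshold also for 27 HIF targets (0 past over all genes, 2 rose adjusted over the list alone; 0.045, 0.587 without siControl replicate 2, 0.237 without siA-3 replicate 1, adjusted p = 0.613 with an estimated correlation), 22 NPM-ALK/STAT3 and ALCL genes (CD274 and the protease inhibitor TIMP1, 0.94, rose; 4 adjusted over the list alone; 0.0286, 0.0672 without siControl replicate 1, 0.128 without siA-3 replicate 2, adjusted p = 0.42 with an estimated correlation) and 26 proliferation genes (0 past on either scale, median -0.22; 0.0242, 0.0817 without siControl replicate 2, 0.0796 without siA-3 replicate 1, adjusted p = 0.199 with an estimated correlation). With siA-1/3 it was for 13 heat shock genes (1 fell adjusted over the list alone; 0.0467, 0.914 without siControl replicate 1, 0.404 without siA-1/3 replicate 1, adjusted p = 0.518 with an estimated correlation), 17 immediate early genes (DUSP1 rose; 4 adjusted over the list alone; 0.0312, 0.106 without siControl replicate 1, 0.308 without siA-1/3 replicate 1, adjusted p = 0.404 with an estimated correlation) and 22 ribosomal protein genes (median -0.12; 0.0117, 0.126 without siA-1/3 replicate 2, adjusted p = 0.404 with an estimated correlation). With siA-1/3 the p53 target GADD45A (1.36) and the cyclin CCNE2 (1.25) rose, in lists not past camera (0.361 and 0.2). With siA-1 against siA-3, 13 AhR and ARNT pathway components had 1 higher and 6 lower (1 and 6 adjusted over the list alone; 0.0247, 0.0915 without siA-1 replicate 1, 0.0597 without siA-1 replicate 2, 0.0809 without siA-3 replicate 2, adjusted p = 0.345 with an estimated correlation), and with TCDD over the 4 siRNAs 13 heat shock genes had a median of -0.14 (1 rose adjusted over the list alone; 0.0121, 0.0681 without siA-1 DMSO replicate 2, 0.0575 without siA-1/3 DMSO replicate 2, adjusted p = 0.554 with an estimated correlation).

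In mouse, random lists ranked the medians of the other lists as follows. For TCDD in Hepa-1c1c7 the percentiles were 57.8 for AhR and ARNT pathway components, 72.6 for hepatocyte identity, 76.8 for other cell types, 67.2 for interferon response, 16.1 for p53 targets, 33.2 for integrated stress response and UPR, 6.14 for heat shock, 1.51 for proliferation, 43.4 for cholesterol synthesis and 98.2 for NF-kB targets. For S77A they were 68.6 for components, 85.3 for other cell types, 2.47 for HIF targets (Vegfa 0.419 and Slc2a3 0.066 as ratios), 7.68 for interferon response, 68.1 for p53 targets, 95.2 for integrated stress response and UPR, 53.6 for proliferation, 97.5 for cholesterol synthesis and 92.1 for NF-kB targets (Tnfaip3 4.34 and Rel 0.432 as ratios).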
